A study of Homo sapiens and Mus musculus with 5 samples.

How the data were processed

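The binding of 5 proteins to DNA was measured on protein-binding microarrays, with 1 array per protein. Full-length human MITF, ETS1, CREB1 and ATF1 and mouse GZF1 had been purified from E. coli or bought, and each carried a HIS, GST or FLAG tag, per the labels. Bound protein was read through the fluorescent label Alexa647. The protein concentrations, incubation, washing and scanner settings are not given in the sources used here.

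The deposited files hold scanner output with 1 row per spot in 1 channel. Per the file headers, each spot has a foreground and a local background intensity (median and mean of its pixels), an intensity after subtraction of the local background, a flag, its row and column, and a foreground intensity normalized by position. The last of these was rebuilt from the files. It equals the foreground median multiplied by the median of the array and divided by the median of a window of 9 × 9 spots around the spot (13 × 13 for ETS1), with a largest relative difference of 4.89e-10. It is not background-subtracted. The series value table held the same numbers, and all 18541 values for MITF and 19725 for each other array were equal. The spots that MITF's file marks as bad, 1184 of 19725, have no value there.

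The signal used was log2 of the position-normalized foreground intensity, with no normalization between arrays. The design had named the background-subtracted column where a file has one. That column was at or below 0 in 4049 ETS1 spots (20.5%), 1491 MITF spots (8.04%), 792 ATF1 spots (4.02%), 13 CREB1 spots and 7 GZF1 spots, which have no log, so the foreground was used. The change was made before any test was run, and the subtracted column was kept as an alternative, with values not above the floor set to the 1st percentile of its positive values. Because foreground that comes from unspecific binding and the slide stays in the signal, log2 effects are smaller than they would be for specific signal alone. For the reference sites the share of signal left above the median of the random sequences is therefore given too. Median foreground over median local background was 6145 over 4494 for MITF, 586 over 513 for ETS1, 2847 over 1678 for CREB1, 3316 over 2324 for ATF1 and 641 over 235 for GZF1. The signal stood least above the slide for ETS1 and most for GZF1.

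Each spot's sequence has 60 bases, with a hairpin stem of 20 base pairs and 5mC written as its own letter. All 687 distinct sequences formed complementary stems. The 789 designed names had 25 spots each, and spots of identical sequence under different names were pooled. Between replicate spots the median SD of log2 signal was 0.176 for MITF, 0.199 for ETS1, 0.120 for CREB1, 0.154 for ATF1 and 0.136 for GZF1, against 0.278, 0.375, 0.259, 0.425 and 0.408 without the position normalization. This spread is technical and says nothing about repeat experiments, and p-values measure it alone. The files mark no batch within an array.

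Sequences were compared within an array in pairs that differ in 1 feature. There were 75 pairs with 5mC on both strands of a CpG, 163 with 5mC on 1 strand of a CpG and 115 with 5mC outside CpG, each against the identical unmethylated sequence. A further 261 pairs set a single-base substitution against its reference site. Background was the 95th percentile of the means of 30 random sequences (15 that may hold 5mC and 15 without), and a pair was tested when at least 1 member was above it. Each pair was fitted with limma (lmFit and eBayes, two-sided), with the variance moderated over all 614 pairs of the array and Benjamini-Hochberg adjustment within array and kind of pair at a threshold of 0.05. CREB1 and ATF1 were compared by the array-by-methylation interaction over the spots of both arrays. The effect of 5mC on both strands was compared with the sum of the single-strand effects by a z test. The 5mC and T effects at a position were correlated with 100000 permutations, and 1000 simulations without effects gave the correlation that shared spots produce. Bootstrap intervals used 2000 resamples of positions or pairs.

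The tests were tried on simulated spots with the real numbers of spots and spread, over the 614 pairs of each array. Pairs without an effect were called in 1.69% to 2.17% of cases. Effects of 0.25 on the log2 scale were recovered in 54.5% of cases for MITF, 74.2% for ETS1, 98.5% for CREB1 and 100% for ATF1 and GZF1, and effects of 0.5 in 89.6%, 95.5%, 100%, 100% and 100%. For the interaction, over 353 pairs, differences of 0.25 were recovered in 96% of cases and pairs without a difference were called in 1.19%.

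The kinds of pair, the limma test, the background and the rule for naming sequences were set before the data were examined. Named per protein are up to 5 unmethylated reference sites with the highest mean and up to 8 methylated variants with the largest increase and up to 8 with the largest decrease among called pairs, within and outside CpG separately, and every methylation state and single 5mC of the highest own reference site. The text gives the leading members and summarises the others. Substitutions, the CpG of further own sites and the sites singled out on another protein's array were chosen after their values were seen. Motif lists, read on both strands, were CACGTG and CATGTG for MITF, CCGGAA and AGGAA for ETS1, TGACGTCA, TGACGT, TGACTCA and TGACGC for CREB1 and ATF1, and GCGCG for GZF1.

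The alternatives planned were normexp background correction (offset 50) followed by the same position normalization, pixel means, a 7 × 7 window, marked spots kept, odd- or even-numbered spots alone, no filter on dim sequences, a background at the array median, and an added threshold of 0.5 on the log2 effect. Chosen after seeing the data were the signal without position normalization, the subtracted signal, leaving out spots more than 3 scaled median absolute deviations from their sequence's median, and the own sites alone for 5mC against T. Control spots entered neither the position normalization nor any test. The planned comparison of 5mC outside the site was not made, since 0 sequences built on a site carry 5mC outside the variable part of the stem. Gene symbols are those of the labels. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1, and figures matplotlib 3.10.9.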

Results

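DNA methylation adds a methyl group to cytosine, most often where cytosine is followed by guanine (CpG), and the resulting 5-methylcytosine (5mC) can change how a transcription factor recognises its site. The series measured the binding of 5 purified full-length transcription factors to a DNA microarray that carries 5mC at chosen positions in chosen binding sites, inside and outside CpG. MITF is a basic helix-loop-helix leucine zipper protein that directs the melanocyte lineage and binds E-boxes. ETS1 belongs to the ETS family, whose winged-helix domain reads a GGAA core. CREB1 and ATF1 are closely related basic leucine zipper (bZIP) proteins that bind the cyclic AMP response element, the palindrome TGACGTCA. GZF1 is a zinc finger protein with a BTB domain. MITF, ETS1, CREB1 and ATF1 are human and GZF1 is from mouse. Each of the 5 proteins was measured on 1 array, so the spread given is that between replicate spots of a sequence on the same array, which is technical, and the number of arrays limits the precision.

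Each array held 20250 spots, of which 19725 carried designed DNA hairpins and 525 were control spots. The hairpins held 687 distinct sequences with a stem of 20 base pairs, and each array had 25 to 150 spots per sequence, except MITF with 19 to 145 after its marked spots were left out. The stems contained 8 designed sites. On the top strand from 5′ to 3′ these were TAGCACGTGCT (MITF site 1), TAGCACGTGAT (MITF reporter site, in other flanks), AGCCGGAAGTT (ETS1 site 1), AGTCGGAAGTT (ETS1 site 2), GGCTGACGTCA (CREB1 site 1), GGATGACGTCA (CREB1 site 2), ACGACGTCGT (CREB1 methylated site, whose reference form carries 4 5mC) and ATTACGGTAAT (GZF1 site 1). Every base of each site had been replaced by each other base and by 5mC on either strand. Adjacent bases had also been turned into CpG in each methylation state. Positions are counted from 1 at the 5′ end of the site's top strand, and a 5mC on the bottom strand is given the position of the guanine opposite it.

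Which of the sites each protein bound was read against 30 random sequences on the same array. MITF, ETS1, CREB1 and ATF1 gave strong signals at their own sites and GZF1 did not. The strongest contrast was that of ETS1, whose mean log2 signal at ETS1 site 1 was 13.11 ± 0.72 (SD, 75 spots), 16.2-fold over the median of the random sequences, against 11.76 ± 0.60 (SD, 75 spots), or 6.40-fold, at ETS1 site 2. MITF reached 14.53 ± 0.18 (SD, 44 spots) at MITF site 1 and 14.67 ± 0.67 (SD, 48 spots) at the MITF reporter site, 4.36-fold and 4.79-fold over random. CREB1 gave 14.50 ± 0.32 (SD, 75 spots) at CREB1 site 2, 13.69 ± 0.36 (SD, 75 spots) at CREB1 site 1 and 12.15 ± 0.18 (SD, 150 spots) at the CREB1 methylated site, which were 9.54-fold, 5.44-fold and 1.87-fold over random. ATF1 ranked the 3 sites in the same order, at 14.05 ± 0.24 (SD, 75 spots), 13.56 ± 0.22 (SD, 75 spots) and 12.09 ± 0.18 (SD, 150 spots), or 5.48-fold, 3.90-fold and 1.41-fold. GZF1 gave 9.50 ± 0.15 (SD, 50 spots) at its own site, 1.27-fold over random.

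A sequence was taken as above background when its mean exceeded the 95th percentile of the random sequences. The number above it was 123 of 687 for MITF, 191 for ETS1, 143 for CREB1, 170 for ATF1 and 8 for GZF1. The GZF1 site stood at 9.50 against a background of 9.64, and 1 of the 91 sequences built on it was above. The brightest GZF1 sequence was one of the random ones, at a mean log2 of 9.96, so the GZF1 array separated no reference site from random DNA at this threshold. The own sites of the other proteins held 51 of 85 and 57 of 87 sequences above background for MITF, 63 of 85 and 60 of 87 for ETS1, and 55 of 85, 68 of 87 and 24 of 78 for CREB1. ATF1 had 66, 71 and 40 above at the same 3 CREB1 sites.

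The motif lists fixed in advance divided the unmethylated sequences in the same way. All 35 sequences with the E-box CACGTG and all 4 with CATGTG were above background for MITF, at a median of 2.13 and 1.30 log2 over random, and none of the 35 with CACGTG was above background for ETS1, CREB1 or ATF1. All 20 sequences with CCGGAA and both with AGGAA were above background for ETS1, at 3.89 and 2.64. All 17 sequences with TGACGTCA were above background for CREB1, at 2.93, and for ATF1, at 2.11. Of the 42 with TGACGT, 41 were above background for CREB1 and 41 for ATF1, while 15 were above background for ETS1. TGACGC put 3 of 8 sequences above background for CREB1 and 8 of 8 for ATF1, although the median over random was higher for CREB1 (0.635 against 0.426 log2). The background lay further above the random median on the CREB1 array (11.93 against 11.25) than on the ATF1 array (11.86 against 11.60), so these counts do not rank the 2 proteins. MITF also had all 3 sequences with GCGCG above background, at 1.31 log2 over random, and GZF1, for which that motif was listed, had 0 of 3. These 3 sequences were MITF site 1 with A5G or T8C and the MITF reporter site with A5G, forms of MITF's own sites with an altered E-box. No sequence held TGACTCA.

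Whether methylation of a whole CpG changes binding was tested by setting each sequence with 5mC on both strands of a CpG against the identical unmethylated sequence. Methylation of the CpG at the center of the recognised element lowered the signal of MITF, CREB1 and ATF1 at their own sites, as did that of the CpG in the ETS1 sites for ETS1. The signal left above random ranged from 1.91% to 20.2% at the 6 sites whose reference carries no 5mC. At MITF site 1, and at CREB1 sites 1 and 2 for CREB1 and ATF1, the methylated sequences were below background. They lay within the range of the random sequences. The methylated ETS1 sites were above background but also within that range, which was 8.98 to 10.16 on the ETS1 array. The shares left at all these sites are therefore approximate, and the error given leaves that range out. At CREB1 site 2 the CREB1 signal fell by 2.81 ± 0.06 on the log2 scale (SE, limma adjusted p = 5.56e-67), and 4.16% ± 0.281 of the signal above the random median was left. The CREB1 change at site 1 was -2.30 ± 0.07 (limma adjusted p = 2.14e-53), with 2.31% left. ATF1 changed by -2.27 ± 0.05 and -1.88 ± 0.05 at the same sites, with 2.96% and 1.91% left. The change was -1.78 ± 0.04 for MITF at site 1 (limma adjusted p = 1.19e-47, 8.00% left) and -1.40 ± 0.14 at the reporter site (limma adjusted p = 6.76e-15, 20.2% left). For ETS1 it was -3.10 ± 0.15 at site 1 (limma adjusted p = 8.89e-38, 5.39% left) and -2.35 ± 0.12 at site 2 (limma adjusted p = 1.29e-34, 4.45% left). The central CpG of the CREB1 methylated site, whose outer CpGs already carried 5mC, changed by -0.71 ± 0.04 for CREB1 and -0.40 ± 0.04 for ATF1. Both signals ended below background. The outer CpGs of that site did not follow: 5mC on both strands gave 0.15 ± 0.04 at position 2 and 0.16 ± 0.04 at position 8 for CREB1, and 0.01 ± 0.04 and 0.13 ± 0.04 for ATF1.

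**Figure D1:**
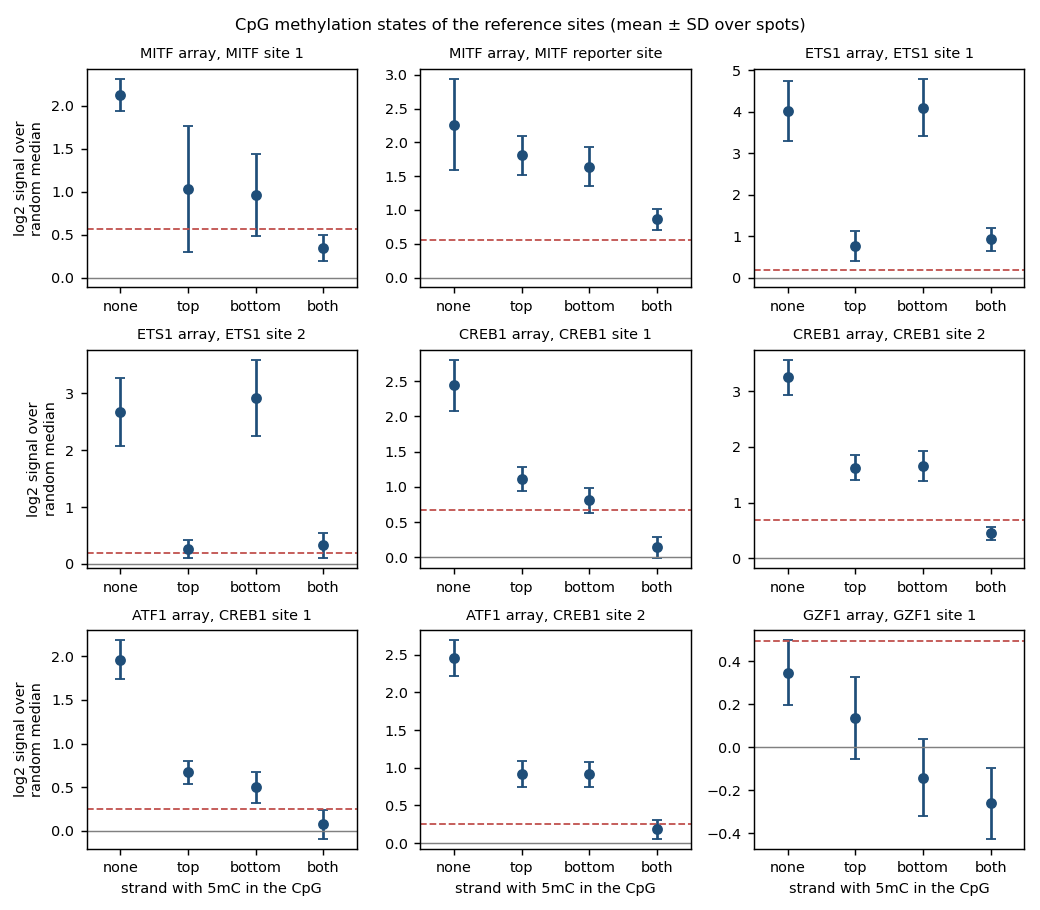
Mean log2 signal over the median of the random sequences for each protein's own reference sites with 5mC on neither strand, the top strand, the bottom strand or both strands of the site's CpG. Error bars are the SD over spots, the gray line marks the random median and the dashed red line the background (95th percentile of the random sequences). ETS1 site 1 stands 4.02 over the random median when unmethylated and GZF1 site 1 stands 0.35 over it, below the dashed line.

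Across all sequences with a CpG above background, the changes of MITF and ETS1 were mostly decreases, while those of CREB1 and ATF1 went both ways. The pairs tested differ between arrays, and directions were not compared between proteins by a test. MITF changed in 9 of 17 tested pairs, of which 9 fell and 0 rose (10 differed at unadjusted p under 0.05 with limma). ETS1 changed in 9 of 23, with 8 falling and 1 rising, against 0 rising and 10 falling after normexp background correction and 0 rising and 8 falling with the local background subtracted. CREB1 changed in 14 of 20 pairs, 10 rising and 4 falling, and ATF1 in 16 of 21, 8 rising and 8 falling. The CREB1 majority of rises depends on the pairs admitted: 17 rose and 27 fell without the filter on dim sequences, 17 rose and 14 fell with the background at the array median, and 2 rose and 3 fell among effects of at least 0.5. At that size 0 rose and 2 fell for ATF1. Of the CpGs made by substitution, the largest CREB1 increase was at site 2 with T9C and C10G, where 5mC on both strands of the new CpG at position 9 raised the signal by 0.93 ± 0.08 (limma adjusted p = 1.39e-15). On the ATF1 array the same change raised it by 0.47 ± 0.05. MITF fell by 1.37 ± 0.10 when the CpG made by G2C and C3G in CREB1 site 1 was methylated (limma adjusted p = 1.05e-21). ETS1 fell by 2.24 ± 0.10 with methylation of the CpG made by G7C and T8G in the MITF reporter site (limma adjusted p = 5.92e-28).

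Within the motif lists, methylation of CpGs in sequences with CACGTG lowered the MITF signal in 4 of 8 pairs and raised it in 0, and 4 fell when adjusted over the list alone. In the 4 pairs with CCGGAA, ETS1 fell in 1, also adjusted over the list alone. The lists count any methylated CpG in a stem that holds the motif. For CCGGAA the median effect was -0.08, while the CpG of the motif in ETS1 site 1 gave -3.10. Sequences with TGACGTCA fell in 3 of 5 pairs for CREB1 and 5 of 5 for ATF1, with the same counts adjusted over the list alone. In the sequences with TGACGC, 4 of 4 pairs rose for CREB1 and 4 of 4 for ATF1, also adjusted over the list alone. There the methylated CpG was a new one, made by T9C and C10G or by G5C and A6G in CREB1 sites 1 and 2. The central CpG at position 7 was not the one methylated in these pairs.

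GZF1 had 4 pairs with a member above background, all at sites of other proteins, and 3 of them fell by 0.15 to 0.18. These calls depend on the processing: with the local background subtracted 0 pairs passed the limma test, and without the position normalization the pair made by A1C and C2G in the CREB1 methylated site gave 0.0258. Among the 71 pairs with neither member above background, 36 passed the limma test adjusted among themselves, and 35 of these fell. The median effect over the 71 was -0.096, so small falls were common on this array. The CpG of GZF1's own site could not be tested under the background filter. Its measured effect was -0.61 ± 0.04 (SE) with 5mC on both strands, the lowest of the 75 pairs of this kind on the array, and -0.387 ± 0.104 without the position normalization. It was the second lowest in that setting and with odd-numbered spots.

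How much of the effect each strand carried was tested with hemimethylated CpGs. ETS1 responded to 5mC on the top strand of its CpG, and no change passed the test for the bottom strand, while MITF, CREB1 and ATF1 responded to either strand. At ETS1 site 1, 5mC on the top strand alone, the strand that reads CCGGAA, changed the signal by -3.26 ± 0.11 (SE, limma adjusted p = 2.03e-57), while 5mC on the bottom strand alone gave 0.08 ± 0.13 (limma adjusted p = 0.691). At ETS1 site 2 the top-strand effect was -2.42 ± 0.09 (limma adjusted p = 1.35e-54) and the bottom-strand effect 0.24 ± 0.11 (limma adjusted p = 0.119). The top effect minus the bottom effect was -3.33 ± 0.11 at site 1 and -2.66 ± 0.10 at site 2. CREB1 changed by -1.63 ± 0.05 (top) and -1.59 ± 0.05 (bottom) at site 2 and by -1.33 ± 0.05 and -1.63 ± 0.05 at site 1, where the strands differed by 0.30 ± 0.03. ATF1 gave -1.54 ± 0.04 for either strand at site 2, and -1.29 ± 0.03 and -1.46 ± 0.04 at site 1, a difference of 0.17 ± 0.03. MITF gave -1.09 ± 0.11 and -1.17 ± 0.08 at site 1 and smaller effects at the reporter site, -0.45 ± 0.10 and -0.62 ± 0.10.

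The effect on both strands was then set against the sum of the single-strand effects on the log2 scale, with a z test on the spot means and Benjamini-Hochberg adjustment within each array. For ATF1 the decrease on both strands was smaller than the sum, by 0.81 ± 0.05 at CREB1 site 2 and 0.87 ± 0.05 at site 1. For CREB1 the shortfall was 0.41 ± 0.07 and 0.66 ± 0.06. At MITF site 1 it was 0.48 ± 0.13, whereas at the MITF reporter site the decrease on both strands exceeded the sum, by -0.32 ± 0.12. The both-strand signals at MITF site 1 and at CREB1 sites 1 and 2 were below background, which limits how far they could fall. Over all own-site CpGs the deviation passed the test in 2 of 12 cases for MITF, 6 of 19 for CREB1, 7 of 20 for ATF1 and 0 of 12 for ETS1, where 0 also differed at unadjusted p under 0.05. The both-strand effect lay above the sum in 3 and below it in 3 of these for CREB1, and above it in 3 and below it in 4 for ATF1. Those below included position 2 of the CREB1 methylated site, -0.34 ± 0.05 for CREB1 and -0.25 ± 0.04 for ATF1, and T4C at site 2, -0.42 ± 0.09 and -0.20 ± 0.07. The strands differed in 5 of 12 cases for MITF, 5 of 12 for ETS1, 15 of 19 for CREB1 and 16 of 20 for ATF1.

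Over all tested pairs with 5mC on 1 strand of a CpG, MITF changed in 19 of 36 (1 rose, 18 fell), ETS1 in 13 of 53 (4 rose, 9 fell), CREB1 in 30 of 42 (16 rose, 14 fell), ATF1 in 37 of 48 (15 rose, 22 fell) and GZF1 in 6 of 8 (0 rose, 6 fell, with 6 at unadjusted p under 0.05 by limma). The GZF1 calls depend on the processing, with 1 left after normexp background correction and 0 by limma with the local background subtracted or without the position normalization. ETS1 had 1 rising and 8 falling with odd-numbered spots, and 0 rising and 7 falling at effects of at least 0.5. For CREB1 23 rose and 44 fell without the filter on dim sequences, and 23 rose and 34 fell with the background at the array median. The CREB1 signal rose by 0.89 ± 0.06 with 5mC on the top strand of the CpG made by T4C at site 2, and by 0.80 ± 0.04 and 0.62 ± 0.04 with 5mC at positions 2 (top) and 9 (bottom) of the CREB1 methylated site. ATF1 rose by 0.63 ± 0.04 with T4C and by 0.51 ± 0.04 at position 2 of the CREB1 methylated site. ETS1 rose by 0.48 ± 0.12 when position 1 (bottom) of CREB1 site 2 was methylated, a CpG that the site forms with its flank (limma adjusted p = 0.000825). The same 5mC gave -0.14 ± 0.08 for CREB1 (limma adjusted p = 0.112) and -0.15 ± 0.05 for ATF1 (limma adjusted p = 0.00500). In the sequences with CACGTG, 7 of 18 MITF pairs fell (6 adjusted over the list alone). In those with TGACGTCA, 5 of 12 fell for CREB1 and 10 of 12 for ATF1, with the same counts adjusted over the list alone.

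The study's title points beyond CpG, and 5mC was also placed where the next base was not guanine. These methyl groups lowered MITF, CREB1 and ATF1 binding at positions inside the core of their sites, and some raised binding. For MITF the position 9 cytosine of the bottom strand was the most sensitive. It gave -1.34 ± 0.14 at site 1 (SE, limma adjusted p = 5.13e-13) and -1.83 ± 0.14 at the reporter site (limma adjusted p = 4.46e-20), where the change at the site's CpG was -1.40. At the mirror position of the E-box, 5mC at position 4 (top) gave -1.01 ± 0.08 and -0.53 ± 0.14. Outside the E-box the effects were small, -0.15 ± 0.05 at position 3 (bottom) of site 1 and -0.04 ± 0.05 at position 10 (top, limma adjusted p = 0.481).

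CREB1 and ATF1 responded to 5mC in the TCA that ends the palindrome on either strand. At position 5 (bottom) CREB1 changed by -1.69 ± 0.07 at site 2 (limma adjusted p = 2.21e-43) and -1.31 ± 0.08 at site 1, and at position 10 (top) by -0.91 ± 0.07 and -1.002 ± 0.08. ATF1 changed by -1.49 ± 0.05 and -1.13 ± 0.05 at position 5 (bottom) and by -0.81 ± 0.06 and -0.80 ± 0.05 at position 10 (top). Between 21.2% and 48.5% of the net signal was left in these 8 cases. At position 2 (bottom), outside the palindrome, CREB1 gave -0.10 ± 0.07 at site 2 (limma adjusted p = 0.2496) and ATF1 -0.14 ± 0.05 (limma adjusted p = 0.0190).

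ETS1 fell by 0.99 ± 0.12 with 5mC at position 3 (top) of site 1 (limma adjusted p = 3.75e-12), and by 0.72 ± 0.16 and 1.06 ± 0.13 with 5mC at position 6 (bottom) of sites 1 and 2, opposite the GGAA core. At position 9 (bottom) it rose by 0.47 ± 0.14 at site 2 (limma adjusted p = 0.00231), and the value at site 1, 0.34 ± 0.16, did not pass the test (limma adjusted p = 0.0731).

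**Figure D2:**
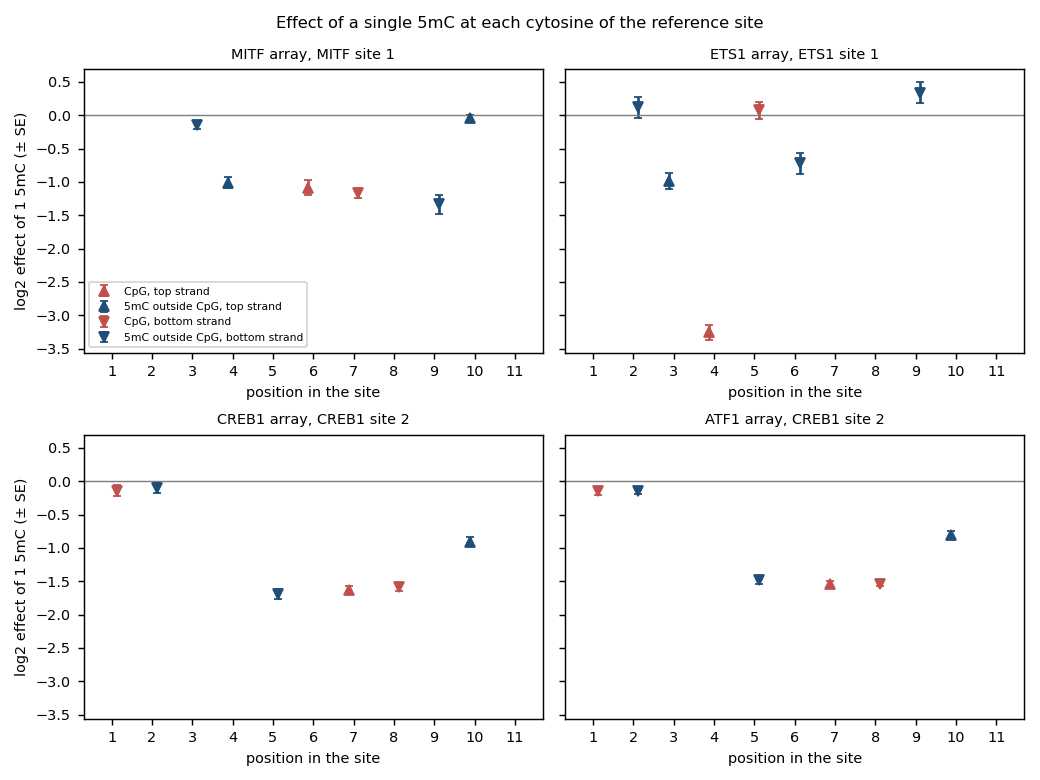
Log2 effect of a single 5mC (mean ± SE) by position along MITF site 1, ETS1 site 1 and CREB1 site 2, the last on the CREB1 and the ATF1 array. Upward triangles mark 5mC on the top strand and downward triangles the bottom strand, in red within CpG and in blue outside it. MITF site 1 shows -1.34 at position 9 outside CpG, and ETS1 site 1 shows -3.26 and 0.08 on the strands of its CpG.

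The largest increases came where a substitution had put a cytosine in place of a thymine of the recognised element. CREB1 site 2 with A6G bound CREB1 at a mean log2 of 11.93, and 5mC on the bottom strand at position 6 raised it by 1.99 ± 0.06, a 3.97-fold gain (limma adjusted p = 1.91e-35). With T9C the gain from 5mC at position 9 (top) was 1.55 ± 0.07, or 2.93-fold. At site 1 the gains were 1.16 ± 0.08 and 1.09 ± 0.05. ATF1 rose by 1.40 ± 0.05, 1.22 ± 0.05, 0.96 ± 0.05 and 0.87 ± 0.04 with the same 4 methyl groups. ETS1 rose by 1.46 ± 0.12, or 2.74-fold, with 5mC at position 8 (bottom) of site 1 carrying A8G (limma adjusted p = 9.66e-15). The MITF increases were smaller, 0.29 ± 0.06 at position 10 (bottom) of site 1 with C10G and 0.23 ± 0.10 at position 3 (top) with G3C (limma adjusted p = 0.0481).

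Over all pairs outside CpG with a member above background, MITF changed in 15 of 27 (2 rose, 13 fell), ETS1 in 16 of 36 (7 rose, 9 fell), CREB1 in 12 of 26 (6 rose, 6 fell) and ATF1 in 16 of 31 (6 rose, 10 fell), against 6 rising and 6 falling for ATF1 after normexp background correction. With the background at the array median 17 rose and 10 fell for CREB1, and at effects of at least 0.5 2 rose and 5 fell for ETS1, 0 rose and 9 fell for MITF and 4 rose and 4 fell for ATF1. GZF1 had 1 testable pair, in which 5mC at position 7 (bottom) of its own site raised the signal by 0.15 ± 0.04 (limma adjusted p = 0.000144) from a level below background. This pair was tested only because its methylated form rose past the background, so a fall there could not have been called. Among the 114 GZF1 pairs of this kind with neither member above background, 11 passed the limma test adjusted among themselves (2 rose, 9 fell). The tested pair had no member above background when pixel means or a 7 × 7 window were used. In the sequences with CACGTG, 2 of 19 MITF pairs rose and 7 fell (1 and 7 adjusted over the list alone). In those with TGACGTCA, CREB1 rose in 1 of 10 and fell in 4, and ATF1 fell in 8 of 10, with the same counts adjusted over the list alone. In those with CCGGAA, ETS1 fell in 4 of 10, also adjusted over the list alone.

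Single-base substitutions gave the scale against which methylation is read. The strongest substitutions within the core of a site gave values as low as methylation of its CpG or lower, and others in the core gave smaller effects. At MITF site 1, and at CREB1 sites 1 and 2 for CREB1 and ATF1, both the lowest substitutions and the methylated CpG were below background. Differences in size between them cannot be ranked there. At ETS1 site 1 every substitution at positions 5 to 7 gave between -4.09 (G5T) and -3.46 (A7T), while A8T gave -0.16 ± 0.16 and G9A -0.04 ± 0.15, neither past the test. The variants at positions 5 to 7 other than A7T were below background, which limits how far their signal could fall. C4T, which places a thymine at the methylated position, gave -3.49 ± 0.14 beside the -3.26 ± 0.11 of 5mC there, and C4A gave -0.69 ± 0.15. T3C in ETS1 site 2, which turns it into site 1, raised the signal by 1.34 ± 0.11. For MITF the substitutions at positions 4 to 9 lay between -2.20 (C6A) and -0.81 (A5G) at site 1 and between -2.52 (C6A) and -0.34 (A5G) at the reporter site, and C10A at site 1 raised the signal by 0.36 ± 0.05. The lowest CREB1 values were -3.07 ± 0.06 for C7A at site 2 and -2.41 ± 0.07 for C7A at site 1, and those of ATF1 were -2.41 ± 0.05 and -1.99 ± 0.05, both for G8T. C3A at CREB1 site 1, which turns it into site 2, raised the CREB1 signal by 0.81 ± 0.05.

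At their own sites 46 of 66 substitutions changed MITF (2 rose, 44 fell), 50 of 66 ETS1 (4 rose, 46 fell), 87 of 96 CREB1 (9 rose, 78 fell) and 89 of 96 ATF1 (9 rose, 80 fell). Counted over all sites, MITF changed in 49 of 69 pairs (5 rose, 44 fell), and with outlying spots left out in 62 pairs (15 rose, 47 fell). With the background at the array median, 33 rose and 101 fell for CREB1, 33 rose and 80 fell for ATF1 and 12 rose and 42 fell for MITF.

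The methylation effect was then compared with that of thymine at the same position, because thymine carries the same methyl group as 5mC. For each position and strand of any site at which the sequence with C, 5mC or T was above background, the 5mC effect was set against the T effect, both relative to C. Sites designed for other proteins gave 24 of the 61 positions for ETS1, 2 of 42 for MITF, 3 of 49 for CREB1 and 1 of 51 for ATF1. The relation was close for CREB1, ATF1 and MITF and weaker for ETS1. Pearson's r across positions was 0.963 for CREB1 (49 positions), 0.972 for ATF1 (51) and 0.877 for MITF (42), each with permutation p = 1e-05, the smallest that 100000 permutations can give, and adjusted p = 1.5e-05. It was 0.524 for ETS1 (61 positions, permutation p = 3e-05, adjusted p = 3.6e-05). Spearman's rho was 0.925, 0.937, 0.807 and 0.314, in that order, with permutation p = 0.0141 and adjusted p = 0.0154 for ETS1. Without the 2 positions farthest from the median T effect, r was 0.959, 0.965, 0.818 and 0.595. At the own sites alone, a comparison chosen after the data were seen, r was 0.962 for CREB1, 0.972 for ATF1, 0.875 for MITF and 0.582 for ETS1 (46, 50, 40 and 37 positions). The p-values were adjusted separately for r and for rho, over all positions, those outside CpG and those within CpG on these arrays. Positions of a site are not independent replicates.

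**Figure D3:**
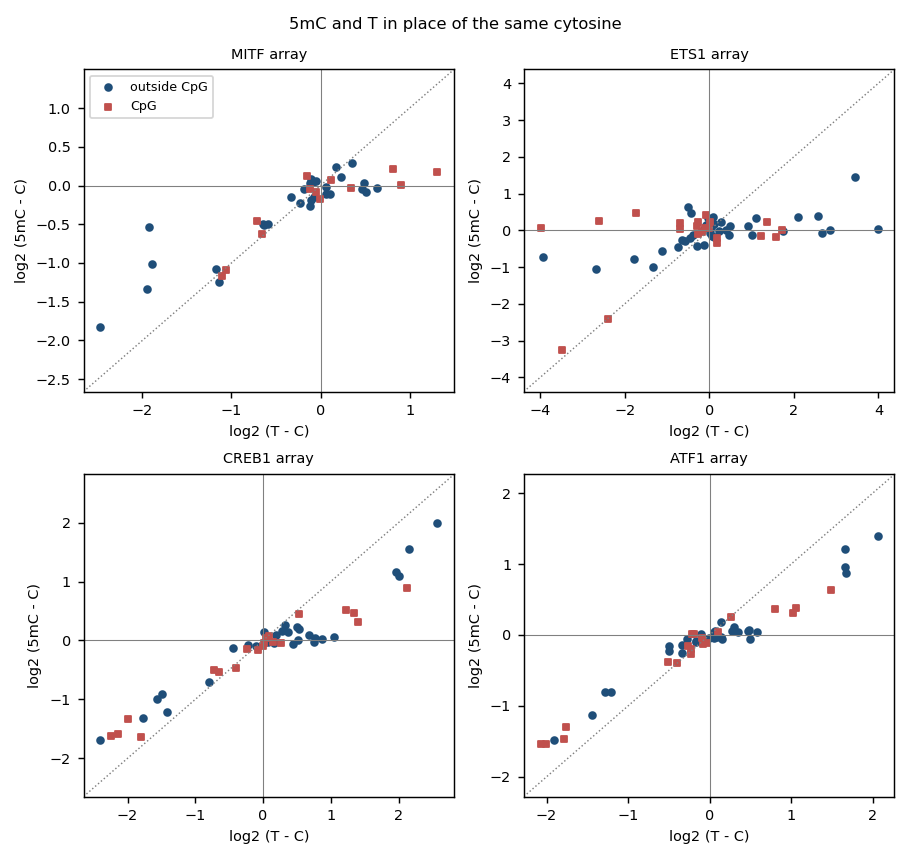
Log2 effect of 5mC relative to C (vertical axis) against the log2 effect of T relative to C (horizontal axis), 1 point per position and strand with a sequence above background, at own sites and sites of other proteins, for MITF, ETS1, CREB1 and ATF1. The dotted line marks equal effects. The points run along a slope below the line for CREB1 (r = 0.963) and ATF1 (r = 0.972), and spread wider for ETS1 (r = 0.524).

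Where T changed the signal by at least 0.5 on the log2 scale, 5mC moved it in the same direction at 28 of 29 positions for CREB1, 19 of 19 for ATF1, 16 of 18 for MITF and 17 of 30 for ETS1 (3 of 11 within CpG). The median share of the T effect that 5mC gave was 60.9%, 66.6%, 71.3% and 14.4%. Outside CpG r was 0.958, 0.969, 0.894 and 0.638, and within CpG it was 0.970, 0.974, 0.848 and 0.451. For ETS1 within CpG rho was -0.135 (permutation p = 0.56) and r without the 2 farthest positions was 0.283. Both of these are at ETS1 site 1. Position 4 (top) went with the relation (T -3.49, 5mC -3.26) and position 5 (bottom) against it (T -3.99, 5mC 0.08). Within CpG, T and 5mC both lowered ETS1 by more than 1 only at position 4 (top) of ETS1 sites 1 and 2 (site 2: -2.40 and -2.42). The relation there therefore rests on few positions.

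Both effects share the spots with C, which alone produces a correlation. Simulation with no effects gave r = 0.377 for CREB1, 0.414 for ATF1, 0.455 for MITF and 0.472 for ETS1, and for ETS1 the upper simulated value, 0.673, exceeded the observed r. With the C spots split between the effects, r was 0.961, 0.970, 0.853 and 0.518. The observed covariance was 0.894, 0.566, 0.348 and 0.524, against 0.00137, 0.000766, 0.00582 and 0.00663 in the simulation. GZF1 had too few positions above background for this comparison.

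CREB1 and ATF1 bind the same element, and their responses to the same methyl groups were compared with an array-by-methylation interaction. The responses were mostly alike in direction and differed in size. Of 85 pairs with a member above background on both arrays, 75 had the same sign, and across pairs r was 0.986 and rho 0.961. The slope of ATF1 on CREB1 effects through the origin was 0.814 (95% bootstrap interval 0.772 to 0.852). The difference passed the limma test in 23 pairs, and in 21 of these the effect was larger on the CREB1 array. In 3 of the 23 the measured effects had opposite signs, all of them small, such as 0.15 on the CREB1 and -0.10 on the ATF1 array for 5mC at position 3 (bottom) of site 1 with C3G. Methylation of both strands of the CpG of CREB1 site 2 lowered the signal by 0.54 more on the CREB1 array (limma adjusted p = 5.35e-09). The methylated sequence was below background on both arrays, which limits how far the signal could fall. The unmethylated site stood 9.54-fold over random for CREB1 and 5.48-fold for ATF1, so this difference does not measure a stronger response. The gain from 5mC at position 6 (bottom) with A6G at site 2 was 0.59 larger on the CREB1 array (limma adjusted p = 1.99e-09). The exceptions included the CpG made by G2C and C3G in CREB1 site 1, where methylation of both strands gave -0.40 for ATF1 and -0.11 for CREB1. By kind of methylation, 8 of 20 pairs differed for CpG on both strands, 10 of 40 for CpG on 1 strand and 5 of 25 outside CpG. The number that passed fell to 2 with normexp background correction, where 21 of the 23 differences kept their direction, and to 4 with the local background subtracted, where 17 of the 23 did. The median size of the 23 differences was 0.254, then 0.252 with normexp and 0.167 with subtraction, and their median SE 0.0655, 0.143 and 0.160. The comparison is between 2 arrays that differ in protein, tag and preparation.

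**Figure D4:**
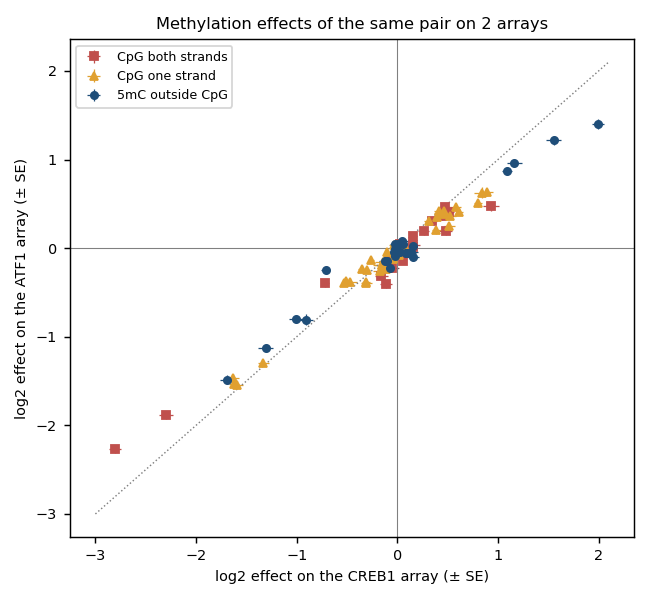
Log2 methylation effect (± SE) of the same pair of sequences on the CREB1 array (horizontal axis) and on the ATF1 array (vertical axis), 1 point per pair with a member above background on both arrays. The dotted line marks equal effects. The 85 points follow a slope of 0.814 through the origin, and 21 of the 23 pairs that differed had the larger effect on the CREB1 array.

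The GZF1 site itself stayed below background, and apart from the 5mC at position 7 (bottom), which rose, changes at it are given as measured values without a call. Substitutions at C5 ranged from -1.09 ± 0.04 (C5A) to -0.99 ± 0.04 (C5T), and those at G7 from -0.96 (G7T) to -0.80 (G7C). At G6 the values were -0.97 (G6A), -1.05 (G6T) and 0.13 (G6C). The median of the 33 substitutions at this site was -0.43, against medians of -0.07 to 0.03 at the other 7 sites on the same array. With 5mC at the CpG of the site, the measured effect was -0.21 ± 0.03 for the top strand, -0.49 ± 0.03 for the bottom strand and -0.61 ± 0.04 for both.

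**Figure D5:**
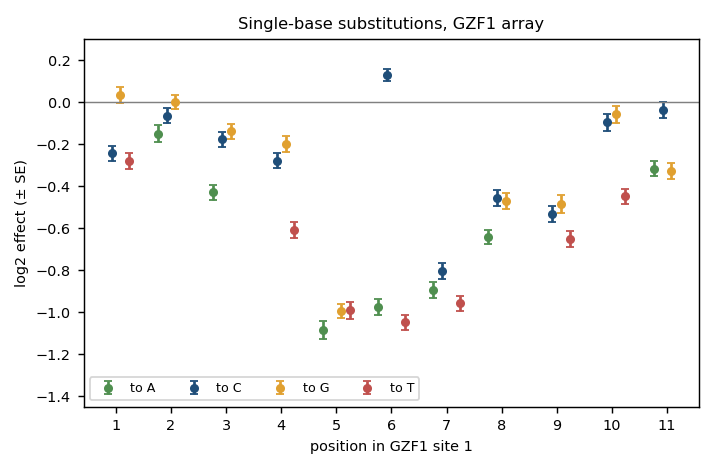
Log2 effect (± SE) of each of the 33 single-base substitutions at GZF1 site 1 on the GZF1 array, by position along the site. The values at position 5 lie near -1.02 and those at position 7 near -0.89, while G6C stands at 0.13.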

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

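The test of plain subtraction in what follows was chosen after the result was seen, and those of scaling and normexp before it.

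The methylation effects of 23 of 85 pairs differed between the CREB1 and the ATF1 array by the limma interaction test. Among the named variants with lower signal after methylation, CREB1 minus ATF1 was -0.54 at the CpG of CREB1 site 2 (both strands), -0.42 at that of site 1 (both strands), -0.17 for 5mC on the bottom strand at position 8 of site 1, -0.32 at the central CpG of the CREB1 methylated site (both strands) and -0.14 for its bottom strand at position 6. With 5mC on both strands of the central CpG, CREB1 sites 1 and 2 and the CREB1 methylated site were below background on both arrays. How far the signal could fall there depended on the sites before this methylation. These stood 5.44-fold (site 1), 9.54-fold (site 2) and 1.87-fold (CREB1 methylated site) over random for CREB1. For ATF1 they stood 3.90-fold, 5.48-fold and 1.41-fold over random. CREB1 minus ATF1 was -0.46 at GZF1 site 1 with T3G and 5mC at position 3 (bottom), where CREB1 gave -0.71 and ATF1 -0.25. Before this 5mC the sequence stood at 12.18 on the CREB1 array, against a background of 11.93. On the ATF1 array it stood at 11.86, level with the background of 11.86, which limited how far that signal could fall. Among those with higher signal it was 0.59 and 0.34 at site 2 with A6G (position 6, bottom) and T9C (position 9, top), 0.22 at site 1 with T9C, 0.46 at the CpG made by T9C and C10G in site 2 (both strands), 0.25 at that made by T4C (top), and 0.29 and 0.21 at positions 2 (top) and 9 (bottom) of the CREB1 methylated site. It was 0.29 for the CpG made by G2C and C3G in site 1 (both strands), where ATF1 had the larger decrease. It was 0.25 for 5mC at position 3 (bottom) of site 1 with C3G, where CREB1 gave 0.15 and ATF1 -0.10.

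The larger effects on the CREB1 array may come from a difference in scale between the 2 arrays. The slope of ATF1 on CREB1 effects was 0.814 for methylation and 0.796 for substitutions (95% intervals 0.772 to 0.852 and 0.781 to 0.812), and dividing ATF1 effects by the substitution slope put 9 of the 23 pairs past the test, 8 with the difference in the same direction and 1 with it turned (from -0.17 to 0.20). The 8 include GZF1 site 1 with T3G and the central CpG of the CREB1 methylated site. At both, how far the signal could fall differed between the arrays. Another 5 pairs passed after scaling, all with the larger scaled effect on ATF1 (differences of 0.11 to 0.34), so 1 common scale leaves part of the pairs unexplained. Background light stays open as a source of that scale. Normexp correction raised the methylation slope to 0.902 (interval 0.860 to 0.935), still below 1. By the bound set in advance this speaks against background light as the whole source, but the rise from 0.814 does not exclude a part. Subtraction, chosen after the result was seen, raised the slope to 0.998 (0.955 to 1.04), an interval that includes 1, so the 2 corrections differ in outcome. The substitution slope moved likewise, to 0.866 (0.842 to 0.888) with normexp and 0.989 (0.954 to 1.02) with subtraction. Protein, tag, preparation and array differ together here, so a biological difference between CREB1 and ATF1, among the 8 pairs too, was not tested apart from them.

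On the ETS1 array, control spots outside the designed sequences were brighter than the designed ones. The median foreground before normalization was 771 at empty control positions and 688 at spike control positions, against 586 over the designed spots. On the other 4 arrays the medians of both kinds of control were below that of the designed spots.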

How the results depend on the processing

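Leaving out outlying spots, the subtracted signal, the signal without position normalization and the own sites alone for 5mC against T were chosen after the results were seen. The fall in signal with methylation of both strands of the own CpG kept its direction and passed the test in every setting run, with ranges of -2.99 to -1.71 (MITF site 1), -1.99 to -1.30 (MITF reporter site), -4.31 to -2.83 and -4.56 to -2.18 (ETS1 sites 1 and 2), -3.84 to -2.24 and -4.05 to -2.76 (CREB1 sites 1 and 2) and -3.40 to -1.83 and -3.78 to -2.18 (ATF1 at the same sites), and at the central CpG of the CREB1 methylated site -1.53 to -0.70 for CREB1 and -1.07 to -0.33 for ATF1. The correlation of 5mC with T effects ranged over 0.813 to 0.890 for MITF, 0.466 to 0.582 for ETS1, 0.940 to 0.963 for CREB1 and 0.955 to 0.974 for ATF1. Counts of calls that moved follow, with the main count after "against" at the earliest mention. Without the filter on dim sequences, by construction more pairs were tested. The calls were then 19 against 9 for MITF (CpG, both strands), 44 against 14, 67 against 30, 39 against 12 and 186 against 90 for CREB1 (CpG on both strands, CpG on 1 strand, outside CpG, substitutions), 153 against 90 for ATF1 substitutions, and 39 against 3, 33 against 6, 12 against 1 and 187 against 1 for GZF1 in the same order, and 37 against 23 pairs differed between CREB1 and ATF1. With the background at the array median, likewise with more pairs, they were 18 for MITF (both strands), 31, 57 and 27 for CREB1 (both strands, 1 strand, outside CpG), and 31, 25, 7 and 138 for GZF1. An added threshold of 0.5 on the effect, which can remove calls and add none, left 7 against 19 (1 strand) and 9 against 15 (outside CpG) for MITF, 7 against 13 and 7 against 16 for ETS1, 5 against 14 (both strands) and 14 against 30 (1 strand) for CREB1, 2 against 16, 7 against 37, 8 against 16 and 54 against 90 for ATF1 in the 4 kinds, 0 in each kind for GZF1 with limma (3, 6, 1 and 1 at unadjusted p under 0.05 without that threshold), and 2 CREB1 and ATF1 differences. With fewer spots per sequence, the odd-numbered ones gave 13 against 8 GZF1 sequences above background, 5 GZF1 both-strand calls and 12 CREB1 and ATF1 differences. The even-numbered ones gave 1, 2, 0 and 2 GZF1 calls (both strands, 1 strand, outside CpG, substitutions) and 10 differences. For the other settings the cause was not tested. Leaving out outlying spots gave MITF 16 (both strands) and 23 (outside CpG) and GZF1 2 (outside CpG) and 2 (substitutions). Without position normalization, calls were 12 for MITF (1 strand), 8 for ATF1 (both strands) and 0, 2 and 2 for GZF1 (1 strand, outside CpG, substitutions), 14 GZF1 sequences were above background, and 6 pairs differed between CREB1 and ATF1. In that setting 3 GZF1 effects turned positive, 0.0258 for the CpG made by A1C and C2G in the CREB1 methylated site (both strands), and 0.0152 (position 2, bottom) and 0.00933 (position 1, top) for the CpG made by T1C and A2G in MITF site 1. Normexp left 1 GZF1 call (1 strand) and 2 CREB1 and ATF1 differences, and subtraction 0 GZF1 calls on both strands, 0 on 1 strand and 4 differences. Pixel means and the 7 × 7 window each left 0 testable GZF1 pairs outside CpG, and so 0 calls. Of 104 named variant effects, those that kept direction and were no longer past the test, or had no member above background, numbered 19 with even-numbered spots, 14 with odd-numbered, 15 each with subtraction and without position normalization, 10 with normexp, 5 with pixel means, 3 with the 7 × 7 window and 2 without outlying spots, and with marked spots kept 2 of 17 for MITF. The GZF1 counts rest on few pairs, since 8 of 687 sequences were above the background set by the random sequences. No paired analysis was possible because each protein has 1 array. The series value table as an alternative changes nothing, as its values equal those used, and alternatives for 5mC outside the site were not run.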

Other observations

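The comparisons of 5mC with T against other bases and the base composition test for GZF1 were tests chosen after the results were seen, as were the substitutions named here on arrays of other proteins.

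ETS1 also bound CREB1 site 2, which reads GAGGCCGGATGACGTCAGCC with its flanks. The mean log2 signal there was 10.88 ± 0.54 (SD, 75 spots), 3.48-fold over random, and 66 of the 87 sequences built on it were above background, against 9.17 ± 0.22 (SD, 75 spots) and 5 of 85 at CREB1 site 1. Each of the 9 substitutions at positions 1 to 3 lowered ETS1 there, with effects of -1.81 to -1.71, while those at positions 9 and 10 lay between -0.08 and 0.11 and none passed the test. C3A, which turns CREB1 site 1 into site 2, raised ETS1 by 1.71 ± 0.07 (SE, limma adjusted p = 4.93e-55). A6T raised ETS1 at CREB1 site 2 by 1.81 ± 0.12 and T4A by 0.53 ± 0.13. 5mC at position 2 (bottom) changed ETS1 there by -0.79 ± 0.12, and at position 5 (bottom) by 0.63 ± 0.13. The largest gain of ETS1 from a substitution was at GZF1 site 1, where T8A raised it by 2.97 ± 0.07 (limma adjusted p = 1.24e-51). The unchanged GZF1 site was below the ETS1 background, at 9.06 against 9.27, as was CREB1 site 1 in the case of C3A, at 9.17. Both gains are therefore measured from a level below background. G9C in the MITF reporter site raised CREB1 by 1.27 ± 0.05, also from a level below background (11.45 against 11.93). 5mC at the new cytosine then changed it by -1.21 ± 0.06, to below background again, which limits how far it could fall.

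At own-site positions with a thymine whose replacement by C lowered the signal by at least 1 on the log2 scale, 5mC in place of C restored a median of 48.8% of the loss for CREB1 (8 positions, all restored in part, 22.3% to 77.4%) and 52.0% for ATF1 (7 positions, 30.05% to 73.3%). For ETS1 the median was 0.965% over 5 positions (-12.8% to 42.2%), and MITF had 1 position, at 13.1%.

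5mC effects followed T effects for MITF, CREB1 and ATF1 and, more weakly, for ETS1 outside CpG, and a candidate explanation is the methyl group that both bases carry. Spots shared between the effects do not account for it, since with these spots split the lowest r of any split on the 4 arrays was 0.503. Outside CpG, a like response to any base change is also argued against for MITF, CREB1 and ATF1. There r with T exceeded the higher of r with A and r with G by 0.353 (95% interval 0.105 to 0.815), 0.515 (0.181 to 0.860) and 0.534 (0.214 to 0.900). For ETS1 the gap was 0.239 (0.00358 to 0.528), the smallest. The resampling took each position and strand as independent, although the strands of a position share sequences. The intervals may thus be too narrow, and that of ETS1, close to 0, does not decide. Within CpG the gaps were -0.0222 for MITF and 0.151 for ETS1, with intervals that include 0, and 0.123 for CREB1 and 0.104 for ATF1, with intervals above 0, so there the explanations cannot be told apart for MITF and ETS1, with 13 and 21 positions. For ETS1 within CpG there is little relation to explain, with rho of -0.135 and the same sign at 3 of 11 positions, and for the others the methyl group's own part stays open.

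GZF1 signal was lower with most substitutions at its own site, by more than with those at other sites, although that site stayed below background, G6C gave 0.13 and 5mC at position 7 (bottom) rose by 0.15. The GZF1 signal at the other sites and random sequences followed the number of G and C in the stem (r = 0.947 over 596 sequences, 0.172 log2 per G or C), which may raise the background above a weak site. With that trend removed the median of the 33 own-site substitutions was -0.449 ± 0.0591 (SE), against medians of -0.0842 to 0.0570 at the other 7 sites, which argues against base composition as its cause. The position normalization was tested at the own CpG alone. Without it the effect there was -0.387 ± 0.104, lowest but 1 of the 75 both-strand pairs, against -0.608 ± 0.037 with it. This argues against the normalization as the source of the fall at that CpG. It does not decide for the substitutions, which the test did not cover. That GZF1 recognises this site weakly stays open as a hypothesis, since no second array or protein amount was measured.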
